A study of Mus musculus with 10 samples.

How the data were processed

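Gene counts were deposited for 10 libraries of mouse auditory cortex, 3 WT and 3 het at 1 month and 2 WT and 2 het at 1 year. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The submitters' processing notes name CASAVA, FastQC, HISAT2, StringTie and edgeR and the build GRCm38; versions, settings and the strand option of counting are not given in the sources used here. The authors deposited raw read counts per gene, and also a series table that holds the same counts with FPKM. The deposited FPKM equals the count divided by a fixed gene length and the library's total gene count within 0.1% for 11523 of 11523 genes with at least 100 counts in 2 or more libraries, which gave the gene lengths used below. Of the genes in the tables, 34344 were found in the GENCODE M21 annotation, 27776 with the same start and end.

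Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered by group with a minimum count of 10 and a minimum total of 15, scaled by TMM, and fitted by robust quasi-likelihood with a mean for each of the 4 groups, so that all 10 libraries share one estimate of the spread (common biological coefficient of variation 0.158). P-values were two-sided and adjusted by Benjamini-Hochberg over 16023 genes with a threshold of 0.05. There were 6 comparisons: het against WT at each age and over both, their interaction with age, and age in each genotype. The standard error of a log2 fold change is its size divided by the square root of F, which is approximate. CPM values are normalized by TMM and given as mean and SD. A floor of 3 counts per library was used where a group had 0 counts, and floors and intervals cover counting error only.

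Before the data were examined 37 gene lists were written, and that of sex chromosome genes served only to check the sex. The other 36 each had at least 5 tested members. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. P-values were adjusted over the 36 lists of a comparison. The genes named were chosen by a rule fixed in advance: Ash1l; the 10 higher and 10 lower with the largest fold change among called genes with a mean of at least 1 CPM and no overlap between libraries, without unnamed predicted genes; the 5 of smallest p where fewer than 5 qualified in a direction; up to 4 members of smallest p in each list described; and up to 10 genes called at both ages. Pisd-ps1, the genes called in both genotypes and the kidney genes other than Kap and Acsm2 were named after their values were seen. The text gives a part of the genes the rule selects, and some genes that the rule selects are not reported here, though all counts include them.

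Libraries were compared before averaging: within a group the chi-square per gene was 11.2 to 31.6, where 1 is expected from sampling noise, so no pair of libraries held the same counts. All libraries held Y-linked transcripts with Xist at no more than 2.24 CPM, matching the labelled sex. The calling was tested on simulated counts drawn from the real means and library sizes. Each gene was drawn independently around its overall mean, with 200 changed genes and 1 gene list shifted besides. The simulated counts held no age effect, no correlation between genes and no structure among the libraries. The shares below therefore do not cover those sources of error. For het against WT at 1 month (15787 genes), 17.1% of 1.5-fold, 65.7% of 2-fold and 91.7% of 4-fold changes were recovered; at 1 year (15754 genes) the shares were 5.71%, 51.4% and 78.3%. Of the calls on simulated counts, 5 of 120 were false at 1 month, 9 of 98 at 1 year, 10 of 130 for age in WT and 5 of 118 for age in het.

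Alternatives tried were other scalings, filters and a fold minimum, DESeq2 1.42.0, limma on FPKM with pseudocounts of 1 and 0.1, fits of the 2 groups alone, the replicate number as a block, and leaving out each library. A correction for gene length was added after seeing the data. No column of the deposited tables was left out.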

Results

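RNA was measured by sequencing of stranded mRNA libraries from the auditory cortex of male C57BL/6 mice. The mice were wild type (WT) or heterozygous for Ash1l (het), which encodes a histone lysine methyltransferase. There were 3 WT and 3 het libraries at 1 month of age and 2 WT and 2 het libraries at 1 year. The 1 year libraries held 11959161 to 13721959 counts. The 1 month libraries held 13715395 to 17252964. Of 34745 genes in each table, 22938 had at least 1 count in any library and 16023 passed the filter on low counts. The labels do not say whether each library came from a separate animal or how the replicates were obtained, so p-values measure only the spread between these libraries. The first principal component held 29.9% of the variance. On it every 1 month library lay below every 1 year library, with het 1 month replicate 1 (4.30) nearest to the 1 year libraries. That library also had the lowest mean correlation with its own group (0.976). Its chi-square per gene was 14.4 with WT 1 month replicate 2, against 30.3 and 31.6 with its own group. With WT 1 year replicates 1 and 2 it was 14.2 and 13.9.

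Ash1l (ENSMUSG00000028053, GRCm38 chromosome 3, 88950622 to 89079375) was measured in every library as a check of the labels. At 1 month it stood at 212 ± 17.6 normalized CPM (counts scaled to the library total; mean ± SD, n = 3) in WT and 143 ± 11.5 (n = 3) in het, with no overlap between the libraries. The het level was 67.8% of WT, a log2 fold change of -0.56 ± 0.10 (SE). At 1 year the levels were 174 ± 12.6 (SD, n = 2) in WT and 159 ± 4.03 (n = 2) in het, or 91.4% of WT, a log2 fold change of -0.13 ± 0.12 (SE). Leaving out one library at a time, the fold change ranged from -0.63 to -0.50 at 1 month and from -0.21 to -0.06 at 1 year. Across all genes the edgeR adjusted p was 0.279 at 1 month and 0.908 at 1 year, so neither difference passed the threshold of 0.05. DESeq2 gave an adjusted p of 0.00166 for Ash1l at 1 month. An exact two-sided permutation test of the 1 month CPM gave 0.1, the smallest value that 3 against 3 libraries allow, and the 1 year test cannot go below 0.333. The change of the difference between the ages was 0.43 ± 0.16 on the log2 scale (unadjusted p = 0.0164, edgeR adjusted p = 0.9996).

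**Figure D1:**
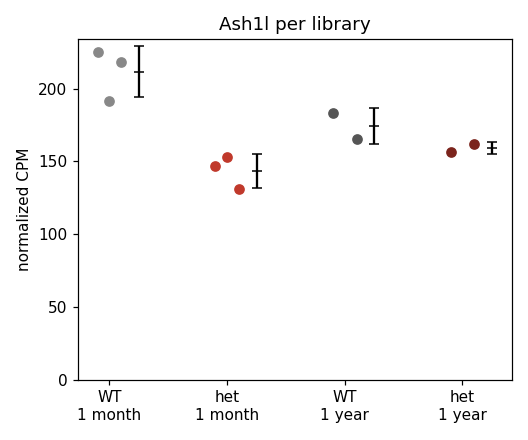
Normalized CPM of Ash1l in each library (points) of the 4 groups, with the group mean (short line) and SD (error bar) beside them; the axis starts at 0. The means lie at 143 in het against 212 in WT at 1 month, and at 159 against 174 at 1 year.

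The comparison of het with WT at 1 month asked which transcripts differ in young heterozygous cortex. The 5 genes with the smallest p included Ash1l. Cldn12, a tight junction claudin, had a log2 fold change of -1.19 ± 0.19. Pik3ca, a catalytic subunit of phosphoinositide kinase, was at -0.82 ± 0.14. Osbp2, an oxysterol-binding protein, was at -0.91 ± 0.15. Kap, a kidney androgen-regulated protein, was at 2.78 ± 0.40. None of them passed the threshold in edgeR, where the adjusted p was 0.266 for Cldn12, Pik3ca, Osbp2 and Kap. In edgeR 0 of 16023 genes passed and 480 had an unadjusted p below 0.05, where p-values spread evenly from 0 to 1 give 801. DESeq2 called 11, among them Ash1l and these 4 in the same directions, with adjusted p of 1.55e-07 for Kap, 1.72e-05 for Cldn12, 0.000224 for Osbp2 and 0.000433 for Pik3ca. The kidney transcript Kap was at 500 counts over the 3 het libraries, 74 over the 3 WT libraries and 0 at 1 year. Listed kidney genes with under 0.5 CPM at 1 year summed to 8.05 ± 4.19 CPM (SD, n = 3) in het and 2.78 ± 0.690 (n = 3) in WT at 1 month. Leaving out one library at a time gave 1 called gene without WT replicate 1, 1 without WT replicate 2, 2 without WT replicate 3, 8 without het replicate 1, 4 without het replicate 2 and 0 without het replicate 3.

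Of 36 gene lists fixed before the data were examined, 10 differed between the genotypes at 1 month by camera with a preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.695 with an estimated correlation). Microglia genes were higher in 22 of 24 members, with a median log2 fold change of 0.14 (adjusted p = 0.000194; adjusted p = 0.695 with an estimated correlation). Among them were the complement subunit C1qb at 0.29 ± 0.13 and the integrin Itgam at 0.31 ± 0.15. Voltage-gated channel genes were lower in 29 of 37 members, with a median of -0.15 (adjusted p = 4.12e-05; adjusted p = 0.695 with an estimated correlation). Kcnq5 was at -0.32 ± 0.10 and Kcnh7 at -0.33 ± 0.14. Haemoglobin and other blood genes had a median of -0.55 over 8 members (adjusted p = 0.0024; adjusted p = 0.695 with an estimated correlation), with Hba-a1 at -0.69 ± 0.21. Myelin genes had a median of -0.15 over 30 members (adjusted p = 0.00617; adjusted p = 0.764 with an estimated correlation), with Mag at -0.32 ± 0.15. Cytosolic ribosomal protein genes were higher in 62 of 81 members with a median of 0.11 (adjusted p = 0.000285; adjusted p = 0.764 with an estimated correlation). The channel list passed with each library left out, its median ranging from -0.21 to -0.07 (adjusted p = 0.0323 without WT replicate 3). The other medians ranged from 0.07 to 0.24 for microglia, -0.66 to -0.38 for blood, -0.34 to 0.00 for myelin and 0.02 to 0.30 for ribosomal protein genes. The microglia call was lost without WT replicate 1 (adjusted p = 0.0958), and the blood call without WT replicate 2 (0.0627) and without het replicate 1 (0.0845). The myelin call was lost without WT replicate 1 (0.236), WT replicate 3 (0.228), het replicate 2 (0.176) and het replicate 3 (0.649). The ribosomal call was lost without WT replicate 1 (0.993), WT replicate 3 (0.315) and het replicate 1 (0.617). The libraries of the genotypes overlapped in each of these lists, by the list's mean log2 CPM relative to all 10 libraries. For microglia it was 0.07 in WT replicate 2, above 0.04 in het replicate 1. For channels it was -0.03 in WT replicate 2, below 0.05 in het replicate 2. For blood it was -0.11 in WT replicate 3 and -0.09 in het replicate 3. For myelin het replicate 1 was highest at 0.26, and for ribosomal protein genes WT replicate 2 was highest at 0.12. No member of these lists passed the threshold over all genes. Adjusted over the list alone, 0 members passed in the microglia, channel, myelin and ribosomal lists and 1 fell in the blood list. The number of lists called was 3 without WT replicate 1, 16 without WT replicate 2, 5 without WT replicate 3 and 6 without het replicate 1.

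**Figure D2:**
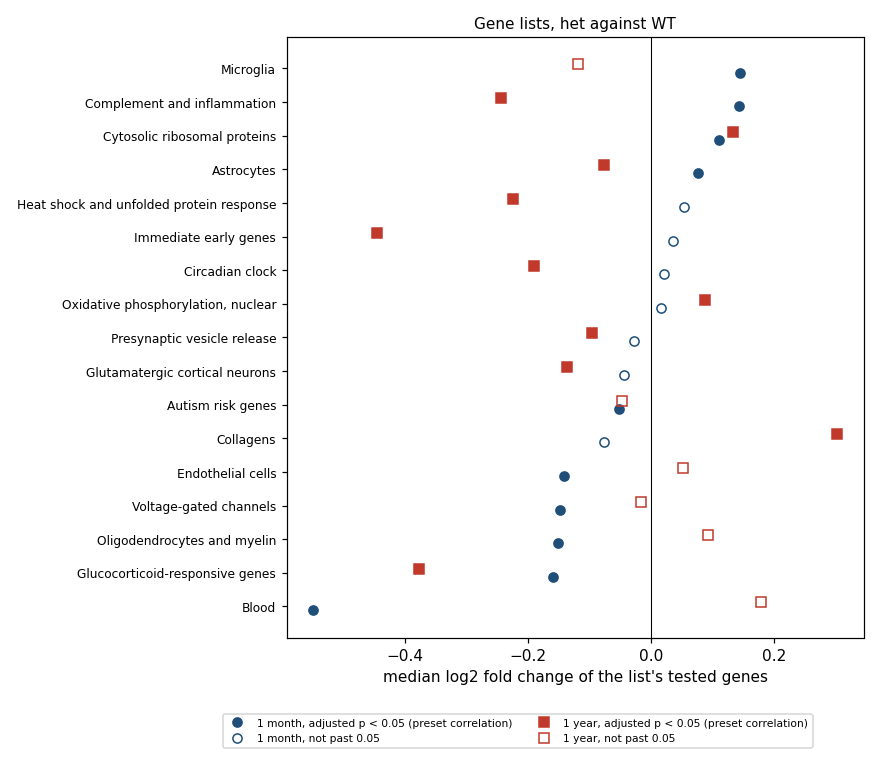
Median log2 fold change, het over WT, of the tested genes of each list called at either age (horizontal axis), at 1 month (circles) and 1 year (squares); filled symbols have an adjusted p below 0.05 with a preset correlation, and no list passes with an estimated correlation. Immediate early genes lie at -0.45 at 1 year and near 0 at 1 month, and blood genes lie at -0.55 at 1 month.

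At 1 year, the predicted gene Gm43796, which overlaps Atp6v0c and Tbc1d24, held 244 counts in the 2 WT libraries and 1 count in the 2 het libraries (edgeR adjusted p = 0.00785). The ratio was 218, with an exact 95% interval from 38.8 to 8663 that covers counting error only. At 1 month Gm43796 was nearly absent in both genotypes, at 0.124 CPM in WT and 0.0231 in het. In WT it rose by 6.01 on the log2 scale from 1 month to 1 year (SE 0.58, edgeR adjusted p = 0.00314). Overlapping genes can share reads, so its count is uncertain, and it did not pass without het replicate 2 (adjusted p = 0.0751). In edgeR 1 gene rose and 1 fell. There were 910 at an unadjusted p below 0.05 where evenly spread p-values give 801, and DESeq2 called 21. Tlr4, a receptor for bacterial lipopolysaccharide, was at -2.81 ± 0.46. Its level of 0.323 CPM in het, against 2.31 in WT, lay near the floor of 3 counts per library (0.242 CPM). Galnt13, a glycosyltransferase, was at -1.10 ± 0.18. Neither passed in edgeR (adjusted p = 0.211 for each), and DESeq2 called both (adjusted p = 0.0312 for Tlr4 and 0.00117 for Galnt13). The count was 8 without WT replicate 1, 6 without WT replicate 2, 10 without het replicate 1 and 5 without het replicate 2, where the lone library left in a group was assumed to vary like the others.

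Immediate early genes, which respond to neuronal activity, were lower in 29 of 30 members at 1 year, with a median of -0.45 (adjusted p = 1.79e-11; adjusted p = 0.465 with an estimated correlation). Egr3 was at -0.66 ± 0.14, Bdnf, a neurotrophin, at -0.42 ± 0.13, and Junb at -0.86 ± 0.31, none past the threshold over all genes in edgeR, while DESeq2 called Egr3 (adjusted p = 0.0403). Glucocorticoid-responsive genes were lower in 19 of 20 members with a median of -0.38 (adjusted p = 5.69e-07; adjusted p = 0.465 with an estimated correlation). Genes of heat shock and the unfolded protein response were lower in 22 of 25 with a median of -0.22 (adjusted p = 1.74e-06; adjusted p = 0.465 with an estimated correlation). The endoplasmic reticulum chaperone Calr was at -0.50 ± 0.12. Collagen genes were higher in 19 of 24 members with a median of 0.30 (adjusted p = 0.00112; adjusted p = 0.729 with an estimated correlation). Among them Col12a1 was at 0.62 ± 0.14. Over all genes 0 members of these 4 lists passed. Adjusted over the list alone, 1 immediate early gene and 1 heat shock gene fell, 1 collagen gene rose and 0 glucocorticoid-responsive genes passed. The first 2 lists passed with each library left out, with medians from -0.58 to -0.37 for immediate early and -0.54 to -0.15 for glucocorticoid-responsive genes. The range was -0.44 to -0.15 for heat shock genes and 0.28 to 0.35 for collagens. The heat shock call was lost without WT replicate 1 (adjusted p = 0.0502) and the collagen call without WT replicate 2 (0.0606). In all, 11 lists were called with the preset correlation, 0 with an estimated correlation, and 4 without WT replicate 1.

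Over both ages 5 het and 5 WT libraries were compared. Meis2, a homeobox transcription factor, was at -0.52 ± 0.08, Pik3ca at -0.65 ± 0.11 and Col12a1 at 0.51 ± 0.09, with edgeR adjusted p of 0.177, 0.284 and 0.288, so none of the 3 passed in edgeR, while DESeq2 called all 3 (adjusted p = 0.000135 for Meis2, 0.000614 for Pik3ca and 0.0106 for Col12a1). In edgeR 1 gene was called. There were 798 genes at an unadjusted p below 0.05 where evenly spread p-values give 801, and DESeq2 called 22. Immediate early genes had a median of -0.26 and were lower in 28 of 30 members (adjusted p = 7.73e-08, and 0.832 with an estimated correlation). This rests on the 1 year libraries. With each library left out, the 1 month median of this list ranged from -0.20 to 0.17, against -0.58 to -0.37 at 1 year. Cytosolic ribosomal protein genes were higher in 78 of 81 with a median of 0.11 (adjusted p = 3.23e-06; adjusted p = 0.832 with an estimated correlation). Adjusted over the list alone, 1 immediate early gene fell and 0 ribosomal protein genes passed. Both lists passed with each library left out, with medians from -0.36 to -0.17 for immediate early and 0.05 to 0.21 for ribosomal protein genes (adjusted p = 0.025 without WT 1 month replicate 1). In all, 9 lists were called with the preset correlation and 0 with an estimated one, with 15 called without WT 1 month replicate 2, 4 without WT 1 month replicate 3 and 4 without WT 1 year replicate 1. The gene count was 3 without WT 1 month replicate 2, 3 without WT 1 month replicate 3, 5 without het 1 month replicate 1, 4 without het 1 month replicate 2, 6 without WT 1 year replicate 1, 5 without WT 1 year replicate 2, 7 without het 1 year replicate 1 and 5 without het 1 year replicate 2.

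The interaction asked whether the genotype difference itself differs between the ages. Immediate early genes had a median of -0.47 (adjusted p = 7.23e-08; adjusted p = 0.452 with an estimated correlation). The median was -0.36 for heat shock and unfolded protein response genes (adjusted p = 2.75e-06; adjusted p = 0.452 with an estimated correlation). It was -0.37 for complement and inflammation genes (adjusted p = 1.33e-05; adjusted p = 0.222 with an estimated correlation). In edgeR 1 gene was called and 668 had an unadjusted p below 0.05 where evenly spread p-values give 801, while DESeq2 called 9. No member of these 3 lists passed over all genes, and adjusted over the list alone 1 complement and inflammation gene fell. The 3 lists passed with each library left out, with medians from -0.62 to -0.33 for immediate early, -0.47 to -0.22 for heat shock and -0.52 to -0.28 for complement and inflammation genes. Of 36 lists, 11 were called with the preset correlation, 0 with an estimated one and 17 without het 1 month replicate 1. The gene count was 2 without WT 1 month replicate 2, 3 without WT 1 month replicate 3, 4 without het 1 month replicate 1, 4 without het 1 month replicate 2, 7 without WT 1 year replicate 1, 3 without WT 1 year replicate 2, 4 without het 1 year replicate 1 and 2 without het 1 year replicate 2. Across the 16023 genes, which are not independent replicates, the genotype differences at 1 month and 1 year correlated with a Pearson r of 0.0424 and a Spearman rho of 0.0525. The value of r was -0.0290 without WT 1 month replicate 3, -0.0202 without het 1 year replicate 1, 0.00910 without WT 1 year replicate 2, 0.0195 without WT 1 year replicate 1, 0.0239 without WT 1 month replicate 1 and 0.0707 without WT 1 month replicate 2.

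In WT, 1 year against 1 month, 9 genes rose and 6 fell (edgeR, 16023 genes). Sema6a, an axon guidance semaphorin, fell by 1.33 on the log2 scale (SE 0.18, adjusted p = 0.0211), and Gpr17, a receptor of oligodendrocyte precursors, by 0.95 (SE 0.15, adjusted p = 0.0394). Nrep, a neuronal protein, fell by 0.98 (SE 0.13, adjusted p = 0.0211). Galnt13 rose by 1.16 ± 0.16 (adjusted p = 0.0211), Rreb1, a zinc finger factor, by 1.12 ± 0.18 (adjusted p = 0.0422) and H2-T22, a major histocompatibility gene, by 0.89 ± 0.14 (adjusted p = 0.0394). PISD and Pisd-ps1, which are near-identical copies that can share reads, rose by 2.54 ± 0.25 and 2.35 ± 0.23. Of Sema6a, Gpr17, Nrep, Galnt13, Rreb1 and H2-T22, all 6 lost the call without WT 1 year replicate 2, with adjusted p from 0.135 for Nrep to 0.356 for Rreb1. All but Nrep lost it without WT 1 month replicate 1 (0.0585 for Sema6a to 0.164 for Rreb1), and all but Galnt13 without WT 1 month replicate 3 (0.0509 for Sema6a to 0.15 for H2-T22). Nrep, Galnt13 and H2-T22 lost it without WT 1 year replicate 1 (0.0744 for Galnt13 to 0.118 for Nrep). DESeq2 called 240 genes and 2452 had an unadjusted p below 0.05. The count was 9 without WT 1 month replicate 1, 97 without WT 1 month replicate 2 and 9 without WT 1 month replicate 3, and age may coincide with a library batch that the labels do not record.

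Cytosolic ribosomal protein genes were higher at 1 year in WT in 75 of 81 members, with a median of 0.37 (adjusted p = 9.16e-18; adjusted p = 0.377 with an estimated correlation). Presynaptic vesicle release genes were lower in 30 of 35, with a median of -0.22 (adjusted p = 3.09e-06; adjusted p = 0.349 with an estimated correlation). The median was -0.59 for mural cells (adjusted p = 0.000139; adjusted p = 0.349 with an estimated correlation). It was -0.42 for endothelial cells (adjusted p = 0.000107; adjusted p = 0.377 with an estimated correlation) and -0.58 for meninges and fibroblasts (adjusted p = 7.84e-05; adjusted p = 0.377 with an estimated correlation). Complement and inflammation genes had a median of 0.40 (adjusted p = 0.00045; adjusted p = 0.349 with an estimated correlation). The complement component C4b was at 1.30 ± 0.24 and Gfap, a marker of reactive astrocytes, at 1.08 ± 0.24, neither past the threshold over all genes. Adjusted over the list alone, 18 ribosomal protein genes rose, 8 presynaptic genes fell, and 6 complement and inflammation genes rose and 2 fell. These 6 lists passed with each WT library left out. Their medians then ranged from 0.25 to 0.59 for ribosomal, -0.29 to -0.13 for presynaptic, -0.71 to -0.48 for mural, -0.53 to -0.21 for endothelial, -0.78 to -0.46 for meningeal and 0.28 to 0.46 for complement genes. In all, 21 lists were called with the preset correlation and 0 with an estimated one. The libraries overlapped in the ribosomal list, by its mean log2 CPM relative to all 10 libraries. That mean was 0.12 in WT 1 month replicate 2, above 0.08 in WT 1 year replicate 1. It was -0.44 and -0.35 in WT 1 month replicates 1 and 3, and 0.26 in WT 1 year replicate 2. The endothelial list overlapped too, at -0.14 in WT 1 month replicate 2 and -0.10 in WT 1 year replicate 1.

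In het, 1 year against 1 month, 295 genes rose and 257 fell (edgeR, 552 in all; 314 and 177 with upper quartile scaling). Met, a receptor tyrosine kinase, fell by 2.08 (SE 0.23, adjusted p = 0.00339). Gpr17 fell by 1.16 (SE 0.15, adjusted p = 0.00775), and Marcksl1, a protein of growing neurites, fell by 1.66 (SE 0.28, adjusted p = 0.03). Kap was at 0 counts in both 1 year het libraries and at 500 counts over the 3 het libraries of 1 month, at least 45.3-fold lower against a floor of 3 counts per library. Acsm2, a mitochondrial acyl-CoA synthetase that is among the kidney genes described below, was at least 11.6-fold lower. By the same floor it was at least 2.79-fold lower in WT. RNA or reads of kidney at 1 month may be the source of both Kap and Acsm2. Col6a2 rose by 0.99 ± 0.16, Rpl10 by 1.04 ± 0.18, and Syn1, a synaptic vesicle protein, fell by 0.80 (SE 0.18). Met and Kap passed with each library left out. Marcksl1 did not pass without het 1 month replicate 2 (adjusted p = 0.0957), het 1 month replicate 3 (0.0954), het 1 year replicate 1 (0.162) or het 1 year replicate 2 (0.174). Acsm2 did not pass without the same libraries (0.0673, 0.0774, 0.162 and 0.149). The count of 552 was 2931 without het 1 month replicate 1, which stood apart on the principal components. It was 26 without het 1 month replicate 2, 19 without het 1 month replicate 3, 21 without het 1 year replicate 1, 22 without het 1 year replicate 2, and 32 with the 2 het groups alone. The counts of 552 and 15 do not show that het changed more with age than WT, since the test of that difference called 1 gene.

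Cytosolic ribosomal protein genes in het had a median of 0.43, with 11 rising and 1 falling over all genes and 26 and 1 adjusted over the list alone (adjusted p = 2.98e-13; adjusted p = 0.504 with an estimated correlation). Presynaptic genes had a median of -0.31 with 6 falling, and 1 rising and 14 falling adjusted over the list alone (adjusted p = 7.11e-06; adjusted p = 0.392 with an estimated correlation). Immediate early genes had a median of -0.52, and 4 fell over all genes and 6 adjusted over the list alone, among them Egr4 by 0.97 (SE 0.20) and Egr1 by 0.80 (SE 0.19) (adjusted p = 1.92e-05; adjusted p = 0.427 with an estimated correlation). Of the heat shock and unfolded protein response genes 5 fell, and 8 adjusted over the list alone, Calr by 0.77 (SE 0.11), with a list median of -0.27 (adjusted p = 2.17e-05; adjusted p = 0.392 with an estimated correlation). In the list of immature neurons 4 genes fell, and 8 adjusted over the list alone, while Dcx, which encodes doublecortin, rose by 0.74 ± 0.16, with a list median of -0.42 (adjusted p = 4.35e-05; adjusted p = 0.392 with an estimated correlation). Of the collagen genes 6 rose, and 9 adjusted over the list alone, with a list median of 0.29 (adjusted p = 0.000385; adjusted p = 0.446 with an estimated correlation). These 6 lists passed with each het library left out. The medians then ranged from 0.34 to 0.53 for ribosomal, -0.34 to -0.26 for presynaptic and -0.66 to -0.25 for immediate early genes. The value of -0.25 is that without 1 month replicate 1 (adjusted p = 0.0109), the library that stood apart. They ranged from -0.41 to -0.30 for heat shock, -0.52 to -0.32 for immature neuron and 0.16 to 0.44 for collagen genes. In all, 16 lists were called with the preset correlation and 0 with an estimated one, and fry called 1, the Eph receptors and ephrins (adjusted p = 0.0289).

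**Figure D3:**
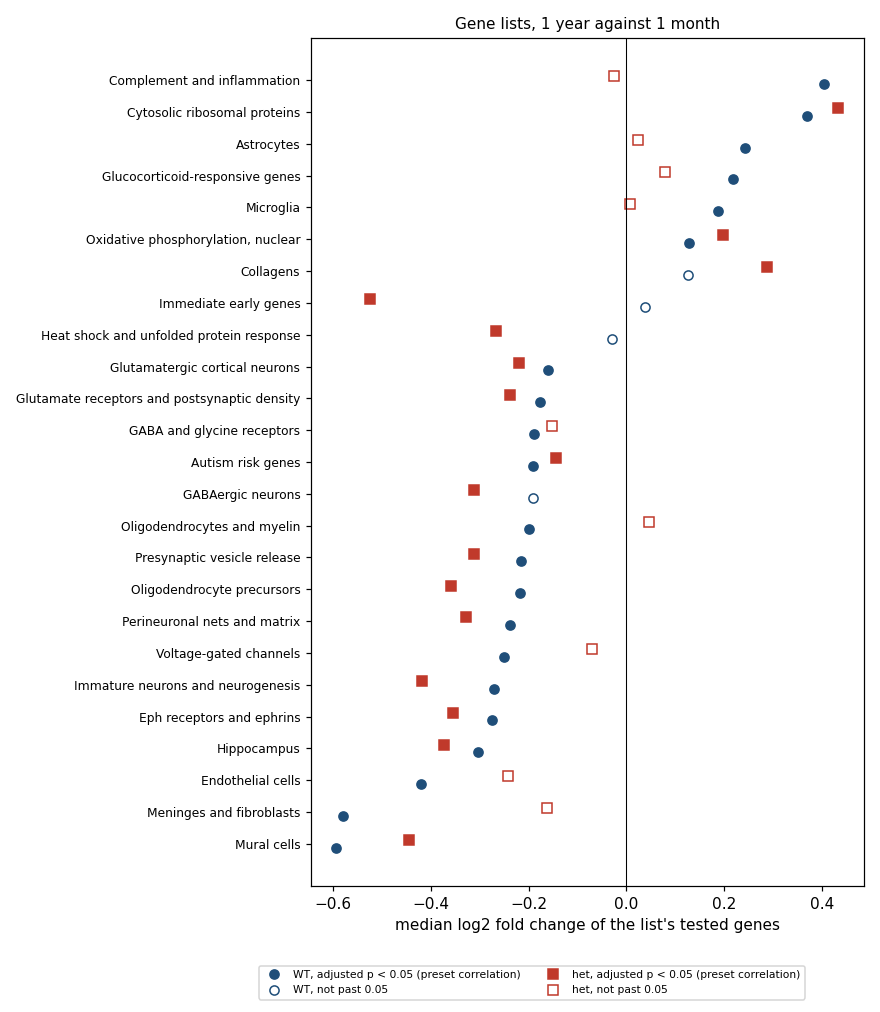
Median log2 fold change, 1 year over 1 month, of the tested genes of each list called in either genotype (horizontal axis), in WT (circles) and het (squares); filled symbols have an adjusted p below 0.05 with a preset correlation, and no list passes with an estimated correlation. Ribosomal protein genes lie at 0.37 in WT and 0.43 in het, and immediate early genes at -0.52 in het.

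The age changes of the genotypes share no libraries. Across the 16023 genes, which are not independent replicates, they correlated with a Pearson r of 0.463 and a Spearman rho of 0.534. Both genotypes called 10 genes in the same direction, 7 rising and 3 falling, where independent calls give 0.166 and 0.0962. The calls are not independent, since they share one estimate of the spread per gene. A batch that coincides with age could also raise the overlap and the correlation. The rising genes included both PISD and Pisd-ps1, near-identical copies that can share reads, so these are not separate genes for this overlap. Among the 10 genes were also Sema6a, Gpr17, Rreb1, H2-T22 and the ribosomal protein gene Rpl12. Rpl12 lost the call without 4 of the 5 libraries in WT (adjusted p from 0.119 to 0.295) and 4 of the 5 in het (0.0749 to 0.149). The correlation was 0.238 without WT 1 year replicate 2 and 0.286 without het 1 year replicate 1.

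**Figure D4:**
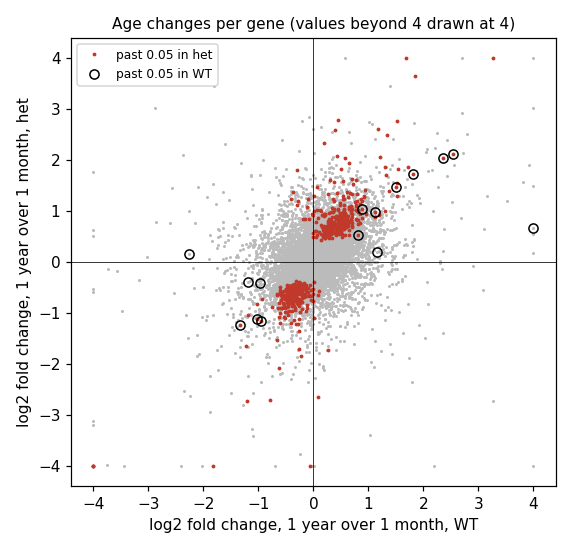
Log2 fold change of each of the 16023 tested genes, 1 year over 1 month, in WT (horizontal axis) and het (vertical axis), with values beyond 4 drawn at 4; red points passed 0.05 in het and circles passed in WT. The genes follow a Pearson r of 0.463, and 10 genes passed in both genotypes.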

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

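The difference between the genotypes differed between the ages for 11 gene lists, by the test of that difference with a preset correlation. The list medians of this difference were -0.47 for immediate early genes, -0.19 for astrocytes, 0.19 for oligodendrocytes and myelin, -0.28 for microglia, 0.62 for blood, 0.15 for voltage-gated channels, 0.36 for collagens, -0.36 for heat shock and the unfolded protein response, -0.30 for glucocorticoid-responsive genes, -0.25 for the circadian clock and -0.37 for complement and inflammation. None of the 11 passed with an estimated correlation, the smallest adjusted p being 0.222 with an estimated correlation. With 1 of the 10 libraries left out at a time, the call with the preset correlation was kept in 6 of 10 cases for blood and for glucocorticoid-responsive genes, 7 for collagens and the circadian clock and 9 for voltage-gated channels, and in all 10 for the other 6 lists. The medians of those 6 then ranged from -0.62 to -0.33 for immediate early genes, -0.30 to -0.16 for astrocytes, 0.08 to 0.46 for oligodendrocytes and myelin, -0.39 to -0.19 for microglia, -0.47 to -0.22 for heat shock and -0.52 to -0.28 for complement and inflammation. Without het 1 year replicate 2 the glucocorticoid median was -0.08 (adjusted p = 0.355).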

How the results depend on the processing

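The gene length correction was chosen after seeing the data. Alternatives were run for 50 results of single genes chosen by the rule fixed in advance, and not for members of lists. None of the 50 changed direction in the alternatives run. Their choice made this likely, since they were picked in these same libraries for large changes without overlap or for small p. Of the values, 163 lost the threshold and 25 gained it, while 633 kept their side. Ash1l was counted apart. The cause was not tested for the following changes. With DESeq2 the counts were 11 at 1 month, 21 at 1 year, 22 over both ages, 9 for the interaction, 240 for age in WT and 1372 for age in het, and Ash1l at 1 month passed at -0.56. With the 2 groups alone they were 2 at 1 month, 15 at 1 year, 79 for age in WT and 32 for age in het, from fewer libraries than in the joint fit. With no filter they were 4 over both ages, 64 for age in WT and 937 for age in het. On log2(FPKM + 1) they were 2 over both ages and 2 for the interaction, and on log2(FPKM + 0.1) 9 for age in WT and 322 for age in het.

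The replicate numbers gave no sign of a pairing of the libraries. After the mean of each group was taken out, same-numbered libraries correlated at -0.0720 to 0.0372 at 1 month and 0.00942 at 1 year. Of 6 libraries of 1 month, 2 correlated best with their own number, which is what chance gives. With 2 or 3 libraries per group these values cannot exclude a pairing. With the replicate block the counts were 2 over both ages, 2 for the interaction, 7 for age in WT and 13 for age in het.

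With an estimated correlation 0 lists were called in each of the 6 comparisons, and with fry 0 in 5 and 1 for age in het. Leaving out one library at a time, gene counts ranged from 0 to 8 at 1 month, 5 to 10 at 1 year, 1 to 7 over both ages, 1 to 7 for the interaction, 9 to 97 for age in WT and 19 to 2931 for age in het. List counts ranged from 3 to 16 at 1 month, 4 to 11 at 1 year, 4 to 15 over both ages, 9 to 17 for the interaction, 15 to 23 for age in WT and 15 to 21 for age in het. The correlation of genotype differences between ages ranged from -0.0290 to 0.0707, its sign turning without WT 1 month replicate 3 (-0.0290) and without het 1 year replicate 1 (-0.0202), and that of age changes from 0.238 to 0.474; over genes with a mean of at least 10 CPM the latter was 0.582. Simulated 2-fold changes were recovered at 51.4% at 1 year and 65.7% at 1 month.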

Other observations

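The tests of gene length, of batch, of the protocadherin gamma genes (2 tests), of the region around Ash1l and of kidney, liver and muscle genes that are low at 1 year were chosen only after the results were seen.

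Other groups also differed between the ages. Oligodendrocyte precursor genes were lower at 1 year, with a median of -0.22 in WT (adjusted p = 0.00287; adjusted p = 0.349 with an estimated correlation) and -0.36 in het (adjusted p = 6.47e-05; adjusted p = 0.392 with an estimated correlation). The WT call was lost without WT 1 year replicate 2 (adjusted p = 0.0527). In het Cacng4, an AMPA receptor auxiliary subunit, fell by 0.83 (SE 0.15, edgeR adjusted p = 0.0279). Genes of glutamate receptors and the postsynaptic density had a median of -0.18 in WT (adjusted p = 0.00174; adjusted p = 0.349 with an estimated correlation) and -0.24 in het (adjusted p = 6.47e-05; adjusted p = 0.392 with an estimated correlation). In het the adhesion protein gene Nlgn3 fell by 0.65 (SE 0.13, edgeR adjusted p = 0.0321) and Gria2, an AMPA receptor subunit, rose by 0.54 ± 0.12 (edgeR adjusted p = 0.0392). Of the precursor genes 1 fell in WT and 2 in het over all genes, and 1 and 7 adjusted over the list alone. Of the postsynaptic genes 0 passed in WT, while 1 rose and 2 fell in het. Adjusted over the list alone, 4 of them fell in WT, and 2 rose and 11 fell in het.

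Genes typical of kidney were present in the 1 month cortex libraries. Kap, Acsm2, Umod and Klk1 were at 500, 126, 76 and 51 counts over the 3 het libraries. They were at 74, 27, 10 and 8 over the 3 WT libraries, and 0 at 1 year. RNA or reads of kidney may be the source, but the test fixed in advance came out against it: the sum of 39 other kidney genes was 1.38 times higher in the 1 month het than in the 1 year libraries, below its bound of 1.5. That bound was wrong, because 96.9% of the 1 year sum came from genes these cortex libraries hold at 0.5 CPM or more, which would hide a small share. Over the remaining 26 genes, a set chosen after that result, the ratio of het to WT at 1 month was 2.89. Liver and muscle as further sources of the excess in het are argued against. Over their genes taken by the same rule the ratio was 0.973 for liver and 0.652 for muscle, and the highest het library stood at 1.35 and 0.875 times the WT mean. The higher of their full sums, that of muscle, was 1.19 times the 1 year level, but 89.2% of its 1 year sum came from genes at 0.5 CPM or more, so this sum alone decides nothing. Other tissues were not tested. The step at which kidney reads would have entered, and a change of these genes in cortex, stay open too.

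Ribosomal protein genes were higher and presynaptic genes lower at 1 year in both genotypes by list median. For the ribosomal genes WT 1 month replicate 2 lay within the range of the 1 year WT libraries. A trend with gene length is argued against as the whole cause: with it removed the list medians kept at least 84.5% of their size and passed with the preset correlation. A library batch that coincides with age cannot be told apart from age, because 0 labels name a batch, date, lane or run. The mitochondrial share of the counts also moved with age: it was 12% to 13.7% in the 1 year libraries and 9.42% to 11.2% in 4 of the 6 libraries of 1 month. It was 13% in WT 1 month replicate 2 and 12.9% in het 1 month replicate 1. RNA or library quality was not tested as a cause and stays open. Ageing stays open as the biological explanation.

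Other splits of the libraries within age were counted. At 1 month the 10 splits are too few for a share under 0.05. The real split called 0 genes and the highest other 5. The real split called 10 lists, the highest other 20, and the median of the other splits was also 10. Over both ages chance is not excluded. Of 60 splits, 39 called at least the 1 gene of the real split (highest other 6). At least its 9 lists were called by 33 of 60 (highest other 19, median of the others 9). A correlation between the ages of at least 0.0424 was given by 12 of 60 (highest other 0.112). At an unadjusted p below 0.05 the real split of 1 month gave 480 genes and the highest other 1843 (median of the others 1121), which points to a structure other than genotype. Over both ages the real split gave 798 genes and the highest other 2184 (median of the others 624). The 801 genes of evenly spread p-values are therefore no firm measure of chance here. WT 1 month replicate 2 and het 1 month replicate 1 resembled each other across genotype, with a chi-square per gene of 14.4. With its own group the former stood at 25.1 and 25.9, and the latter at 31.6 and 30.3. Both also had a mitochondrial share near that of the 1 year libraries, as given above. Why these 2 libraries resemble each other was not identified.

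Of 403 tested genes near Ash1l on chromosome 3, leaving out Ash1l and genes there whose values had been seen earlier, 4.22% had an unadjusted p below 0.05 over both ages, against 4.96% of 15548 genes elsewhere (two-sided Fisher exact p = 0.562).

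In the protocadherin gamma cluster, where genes share exons, single members were high in some libraries and low in others. The coefficient of variation of the cluster sum over the 10 libraries was 0.215 times the median of its 22 members. This ratio alone decides nothing, since 36.9% of 10000 shuffles of each member over the libraries met the bound set for it without any exchange of reads. The coefficient itself was 0.181, and 2.06% of the shuffles gave one as low (median 0.303), consistent with reads moving between members. A true shift of expression between members stays open.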
